A study of Mus musculus with 23 samples.

How the data were processed

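RNA sequencing profiles of 23 libraries were analysed, 14 from tumors of IL6Myc transgenic mice and 9 from B cells of wild-type mice. IL6Myc mice develop tumors of plasma cells, the antibody-secreting end stage of the B cell lineage. Per the labels, total RNA was extracted with a column kit and made into stranded libraries, and every tissue sample went through magnetic negative selection for B cells before extraction. Negative selection removes cells that carry markers of other lineages, so cells that escape the beads stay in the sample. The labels place 7 libraries in tumors of the mesenteric lymph node (MLN) and 7 in spleen tumors. They place 4 libraries in quiescent splenic B cells and 5 in splenic B cells cultured with 1 µg/ml lipopolysaccharide (LPS, a bacterial mitogen) for 16 hours, here called activated.

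The deposited table holds estimated counts, 1 value per gene and library, although its name speaks of TPM. The values were not whole, and their totals, after identical entries were merged, lay between 13328866 and 25045814 per library. TPM has a fixed and far lower total, so the unit was set as estimated counts from the values. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.0, DESeq2 was used and the genome build was GRCm39. The quantifier and the step that gave mouse genes human names are not given in the sources used here. No coordinates are printed, because the reference annotation at hand is of another build.

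The table lists 61651 entries under human gene symbols, of which 21282 carry values. After removal of entries at 0 in every library, 17047 remained, and entries with identical values were merged into 15881 profiles. Of these, 468 carried more than 1 human name, and 532 human names were carried by more than 1 profile. Where a name had several profiles, the one with the highest mean over libraries was used, and values of such families are uncertain as to the mouse gene. CDKN2A, IGHD and the IGHG genes had no values and were not analysed here. IGHA1 and IGHA2 share 1 profile, which stands for the single mouse alpha heavy chain gene. Human V gene names mark mouse V genes only as ortholog labels.

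The values were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, 2-sided) in R 4.3.3. The design fixed before the data were examined had assumed TPM and named limma on log2 values, so edgeR was chosen after the unit was seen. The planned limma test was run as an alternative with limma 3.58.1, and DESeq2 1.42.0 was added as another. Genes at 1 CPM (counts scaled to a common library total) or more in at least 4 libraries were tested, which left 11637. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Adjusted p-values of genes are edgeR's and those of lists camera's unless another tool is named. CPM values in the comparisons are scaled by TMM. The value after ± on a log2 change, named SE, is the absolute log2 change divided by the square root of edgeR's F statistic. It is an approximate standard error, least reliable for genes near 0 in a group.

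The mouse was the replicate. Equal numbers in the labels mark tumors of 1 animal, 6 of the 8 tumor mice gave both tumors, and their counts were summed, so the comparisons with control B cells used 8 tumor mice, 5 activated and 4 quiescent libraries in 1 fit. MLN and spleen tumors were compared over the 14 tumor libraries, with the mouse as a block over the 6 pairs as the alternative. The pairing comes from the series' design text. The deviations of paired tumors from their tissue means correlated at -0.22, -0.33, 0.5, -0.2, -0.44 and 0.67 for mice 1610, 1611, 1613, 1614, 1615 and 1616. The labels do not say whether control libraries came from separate animals, so p-values against them may measure technical spread.

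Gene lists fixed beforehand covered plasma cell identity, mature B cell identity, the unfolded protein response and secretion, MYC targets, the cell cycle and the IL6-STAT3 response as core lists. Further lists covered NF-kB targets, B cell activation, myeloma-associated genes, myeloma drug and antibody targets, trafficking and adhesion, the BCL2 family, interferon response, glycolysis, oxidative phosphorylation, amino acid and one-carbon metabolism, polycomb and chromatin, and ribosomal proteins. Marker lists covered T, NK, macrophage, neutrophil, erythroid, dendritic, platelet, stromal, adipocyte, exocrine pancreas and intestinal epithelium cells. Lists were tested with camera (preset correlation 0.01, and again with an estimated one) and with fry, adjusted over 116 tests. Of these, camera called 62 with the preset correlation and 0 with an estimated one, and fry called 71.

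Genes named in the text follow a rule fixed beforehand, with CPM in place of TPM. A set of model, plasma cell and B cell genes is always named. Some genes of this set and 1 gene list were tested with the others but are not reported here. In each comparison the 8 largest rises and falls were eligible among genes past the threshold, at 10 CPM or more in the higher group and with no overlap between groups, a condition dropped for MLN against spleen tumors. Immunoglobulin and T cell receptor genes, mitochondrial genes, small and ribosomal RNAs and predicted genes were left out of these. Of each core list up to 4 and of each other list up to 2 called members with the largest changes were eligible. Genes named outside this rule are marked as chosen after their values were seen. A fold against a group at 0 is given as a lower bound, with 3 counts over that group as the floor. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Shares of single libraries carry 95% Wilson intervals. Intervals and floors cover counting error only.

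V gene usage was taken as each V profile's share of the summed heavy (IGHV) or kappa (IGKV) V counts of a library, averaged over the tumors of a mouse. Group means were compared by 2-sided exact permutation of labels, and pairings of MLN and spleen tumors by 1-sided exact permutation over 720 pairings. Marker coherence was set against 10000 random lists of matched expression. SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15 were used for these tests, and matplotlib 3.10.9 for the plots.

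The count test was tested on simulated counts for 11637 genes, of which 200 were changed. At 2-fold it found 52.2% of changed genes for tumors against quiescent cells, 50.7% for tumors against activated cells, 70.1% for activated against quiescent cells and 23.9% for MLN against spleen tumors. At 4-fold the shares were 83.3%, 86.4%, 83.3% and 53%, and at 1.5-fold 9%, 16.4%, 61.2% and 1.5%. Each simulated fit held only the groups compared. In the comparisons that involve control groups far more than 200 genes passed in the data, so there the shares do not give the power of the tests on these data. Alternatives covered other scalings, filters, pseudocounts, tools, fits restricted to some groups or to 1 tissue, leaving out each mouse or control library, and blocks on the replicate number. Another took the level of Y-linked genes as a covariate. That level hardly varied within either control group, so the slope of this covariate rests on the tumor mice. The medians of log2 changes over all genes tested were 0.08 for tumors against quiescent cells, 0.09 for tumors against activated cells and -0.15 for activated against quiescent cells. With quantile normalization they were -0.08, -0.10 and -0.03.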

Results

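The data are gene-level RNA sequencing counts of 23 libraries in 4 groups: 7 MLN tumors, 7 spleen tumors, 4 quiescent and 5 LPS-activated B cell libraries. Mice 1610, 1611 and 1613 to 1616 gave both tumors, mouse 1609 an MLN tumor only and mouse 1612 a spleen tumor only. The total of estimated counts per library lay between 14712392 and 21897188 in MLN tumors and between 13328866 and 20091467 in spleen tumors. It lay between 15529618 and 24226060 in quiescent and between 20194017 and 25045814 in activated B cells. Between 12010 and 14195 profiles were above 0 in a library. Correlations of log2 values between libraries of 1 group ranged from 0.9969 to 0.998 in activated cells, 0.9938 to 0.9971 in quiescent cells, 0.9192 to 0.9825 in MLN tumors and 0.8799 to 0.9911 in spleen tumors. Immunoglobulin genes took 11.8% ± 9.73 (SD, n = 7) of the counts in MLN tumors, 7.35% ± 7.5 (SD, n = 7) in spleen tumors, 2.48% ± 0.243 (SD, n = 4) in quiescent and 0.763% ± 0.0578 (SD, n = 5) in activated cells. Some tumors lay below the lowest quiescent library (2.24%). These were the spleen tumors of mice 1610, 1612 and 1615 (1.13%, 1.66% and 1.03%) and the MLN tumor of mouse 1611 (2.01%). In those spleen tumors the mean log2 level of plasma cell genes was 5.08, 5.78 and 5.41 (quiescent 5.29 to 5.43). That of B cell genes was 9.27, 9.0 and 9.05 (quiescent 9.6 to 9.65), so by these lists they lay near B cells.

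The comparison of tumors with quiescent B cells asks how the tumor samples differ from resting cells of the B cell lineage. MYC, a transcription factor that drives growth and carries the model's name, averaged 795 ± 435 CPM (SD, n = 8) in tumor mice and 72.5 ± 6.79 CPM (SD, n = 4) in quiescent cells. It rose by 3.45 ± 0.34 on the log2 scale (SE, adjusted p = 8.71e-07). MKI67, a gene of dividing cells, rose from 25.8 ± 1.36 CPM (SD, n = 4) to 552 ± 147 CPM (SD, n = 8), a log2 change of 4.42 ± 0.23 (SE, adjusted p = 7.61e-09). The plasma cell genes SDC1 (log2 change 2.47 ± 0.55, adjusted p = 0.00103), PRDM1 (2.60 ± 0.45, adjusted p = 0.000124) and XBP1 (2.67 ± 0.57, adjusted p = 0.000746) rose. The alpha heavy chain gene IGHA1 rose from 235 ± 130 to 40600 ± 54300 CPM. The B cell genes PAX5 (-1.44 ± 0.32, adjusted p = 0.00103) and MS4A1 (-1.45 ± 0.32, adjusted p = 0.000848) fell, as did IGHM (-1.99 ± 0.43, adjusted p = 0.000799). IRF4, TNFRSF17, SLAMF7, CCND1 and CCND3 did not pass the threshold, with adjusted p of 0.153, 0.183, 0.0569, 0.119 and 0.154. Their lowest adjusted p over alternatives were 0.0423, 0.0503, 0.0105, 0.0204 and 0.00129, so all but TNFRSF17 passed in some setting. CCND2 rose by 2.51 ± 0.40 (adjusted p = 5.68e-05), while CD38 (-0.67 ± 0.15), MCL1 (-0.46 ± 0.10) and BCL2 (-1.34 ± 0.30) fell. In spleen tumors alone, the calls of PAX5, MS4A1 and CD38 were lost, at adjusted p of 0.154, 0.154 and 0.179, which were the highest over their alternatives (lowest 2.09e-05, 3.36e-05 and 3.87e-05), while the log2 changes were -1.48, -1.44 and -0.56. With the 14 tumor libraries taken as independent PAX5 and MS4A1 did not pass either (0.0638 and 0.0503). Without mouse 1616 the log2 changes of XBP1 and IGHA1 were 2.07 and 6.70, against 2.67 and 7.43 with it.

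Over all genes, 7998 of 11637 passed the threshold in edgeR, 4289 higher and 3709 lower in tumors. The higher genes made up 53.6% of these, but 41.8% with quantile normalization and 77.9% with a filter of at least 2-fold. Of the genes called, 5508 had no overlap between the groups, which chance gives to 0.404% of genes. Among the largest rises, the receptor gene EPHA8 was 1740-fold higher by its counts (95% counting interval 594 to 8420), the respiratory chain gene COX4I2 at least 588-fold and the neuropeptide gene NTS at least 272-fold. The complement inhibitor SERPING1 averaged 299 ± 682 CPM against 0.269 ± 0.105. Without mouse 1616 the fitted log2 change of SERPING1 was 7.73 in place of 10.09 and that of COX4I2 11.5 in place of 12.25, and without quiescent library 3 that of EPHA8 was 13.82 in place of 10.58. The largest falls included the transporter SLC4A11 (-3.22 ± 0.30, adjusted p = 4.99e-07), the enzyme GAD1 (-3.06 ± 0.34, adjusted p = 2.43e-06) and the adhesion molecule L1CAM (-2.85 ± 0.21, adjusted p = 6.09e-08).

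Of 6 core lists, 5 passed in camera with the preset correlation. Of 34 cell cycle genes tested, 33 were higher (33 adjusted over the list alone) and 0 lower, at a median log2 change of 3.67 (camera adjusted p = 1.78e-34, adjusted p = 0.234 with an estimated correlation). CDC6 rose by 4.79 ± 0.31 and BIRC5 by 4.76 ± 0.33. Of 50 MYC targets, 42 were higher (44 adjusted over the list alone), at a median of 0.89 (camera adjusted p = 7.84e-12, adjusted p = 0.533 with an estimated correlation). The polyamine enzyme SRM rose by 2.39 ± 0.33. Of 17 plasma cell genes, 13 were higher (15 adjusted over the list alone), at a median of 2.47 (camera adjusted p = 0.00218, adjusted p = 0.638 with an estimated correlation), with CD28 up by 5.63 ± 0.72. Of 31 genes of the unfolded protein response and secretion, 26 were higher (28 adjusted over the list alone), at a median of 1.58 (camera adjusted p = 0.000772, adjusted p = 0.666 with an estimated correlation). The secretory gene CRELD2 rose by 3.44 ± 0.68, or by 2.71 without mouse 1616. Of 24 mature B cell genes, 22 were lower (23 adjusted over the list alone), at a median of -1.32 (camera adjusted p = 2.26e-06, adjusted p = 0.533 with an estimated correlation). The complement receptor CR2 changed by -2.70 ± 0.43 and the IgE receptor FCER2 by -2.21 ± 0.31. With spleen tumors alone 4 of the 24 were lower, and with the 14 tumor libraries taken as independent 10. The IL6-STAT3 list did not pass in camera (adjusted p = 0.106, adjusted p = 0.533 with an estimated correlation) and did in fry (adjusted p = 0.000165). Of its 24 members, 13 were higher and 5 lower (the same adjusted over the list alone), with VEGFA (5.68 ± 0.77) and BCL2L1 (2.89 ± 0.52) among the higher. IL6 itself was low in tumors, at 0.601 ± 0.317 CPM (SD, n = 8), against 3 counts in quiescent cells, a ratio of 14.8 (95% counting interval 4.98 to 72.8). Its call (adjusted p = 0.000214) was lost with quantile normalization (0.378) and a pseudocount of 5 (0.133), over a range of 2.92e-05 to 0.378. Without quiescent library 2 its log2 change was 4.62, against 3.75. Markers of other cell types rose beside the core lists, with 13 of 14 macrophage, 9 of 9 neutrophil, 8 of 8 erythroid and 12 of 13 stromal genes higher in edgeR (the same adjusted over the list alone). Whether reads of an IL6 transgene are counted here is not given in the sources used here.

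**Figure D1:**
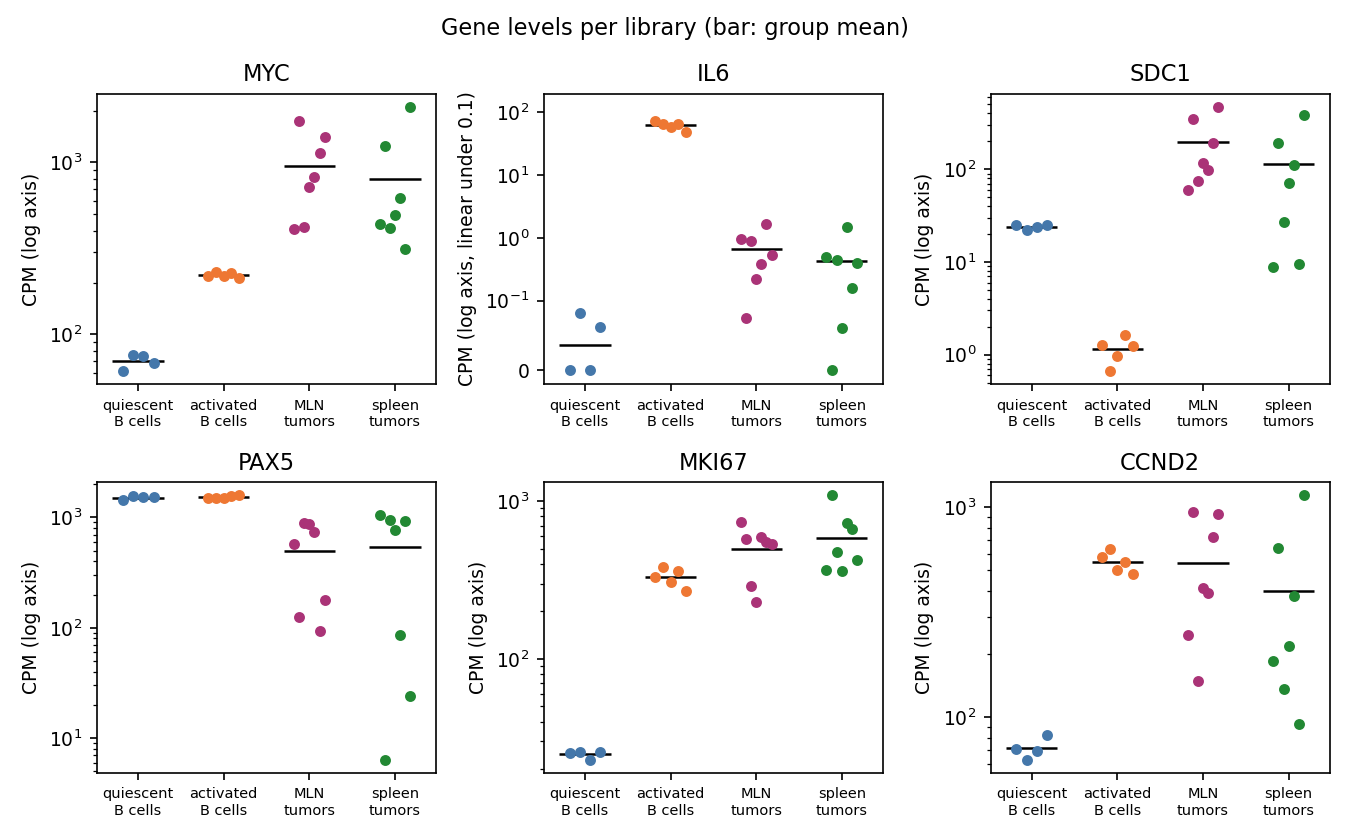
CPM on a log axis (for IL6 linear under 0.1) of MYC, IL6, SDC1, PAX5, MKI67 and CCND2 in each library, with a bar at each group mean. MYC averaged 795 CPM in tumor mice, 220 in activated and 72.5 in quiescent B cells, while IL6 was highest in activated B cells at 62.1 CPM.

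The comparison of tumors with LPS-activated B cells sets the tumors against dividing cells of the lineage. MYC was higher in tumors than in activated cells, which averaged 220 ± 7.14 CPM (SD, n = 5), by 1.86 ± 0.29 on the log2 scale (SE, adjusted p = 3.76e-05). SDC1, the surface marker of plasma cells, rose from 1.14 ± 0.355 CPM (SD, n = 5) to 138 ± 133 CPM (SD, n = 8), a log2 change of 6.91 ± 0.66 (adjusted p = 3.26e-07). TNFRSF17, a receptor on plasma cells, rose by 6.35 ± 0.88 (adjusted p = 1.35e-05), and the joining chain JCHAIN by 5.79 ± 0.70. IL6 was lower in tumors, by -6.68 ± 0.35 (adjusted p = 3.44e-10), and activated cells averaged 62.1 ± 8.76 CPM. The cytokine-induced genes CISH (-6.64 ± 0.33, 4.41 ± 1.98 against 445 ± 19.3 CPM) and NFIL3 (-4.61 ± 0.20, 20.4 ± 7.01 against 500 ± 15.1 CPM) fell among the most. CCND1 rose by 5.43 ± 0.68, BCL2 (-1.15 ± 0.28, adjusted p = 0.00213) fell, and CCND2, CCND3, SLAMF7, CD38 and IGHM did not pass, with adjusted p of 0.325, 0.998, 0.495, 0.0651 and 0.412. Their lowest adjusted p over alternatives were 0.00193, 0.174, 0.114, 0.0193 and 0.0145, so CCND2, CD38 and IGHM passed in some setting. Without activated library 5 the log2 change of CCND1 was 6.58, without activated library 4 that of TNFRSF17 was 7.20, and without mouse 1616 those of SDC1 and JCHAIN were 6.24 and 5.06. XBP1 (1.23 ± 0.48, adjusted p = 0.035) and IRF4 (1.02 ± 0.36, adjusted p = 0.0216) passed, but XBP1 lost its call without mouse 1616 (log2 change 0.53, adjusted p = 0.107) and without any of the activated libraries (0.0607 to 0.0642). The adjusted p over their alternatives ran from 0.00726 to 0.684 for XBP1 and from 0.00535 to 0.972 for IRF4. With the level of Y-linked genes as a covariate the log2 changes turned to -0.46 for XBP1 and -0.03 for IRF4 (adjusted p of 0.684 and 0.972), so that fit shows no direction for them.

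Over all genes, 7357 passed in edgeR, 4214 higher and 3143 lower in tumors. The higher genes made up 57.3%, but 39.7% with quantile normalization and 84.3% with a filter of at least 2-fold. Of the genes called, 4635 had no overlap between groups, against a chance share of 0.155% of genes. The largest rises were in genes with 0 counts in activated cells, the erythroid antigen gene KEL (at least 963-fold), the myeloid receptor CD300C (at least 844-fold) and the enzyme GCNT2 (at least 725-fold). Markers of other blood cells were higher as well. These were macrophage genes for 14 of 14 (14 adjusted over the list alone, median log2 change 8.24, camera adjusted p = 2.06e-07, adjusted p = 0.425 with an estimated correlation), erythroid genes for 8 of 8 (8 adjusted over the list alone, median 9.34, camera adjusted p = 0.000855, adjusted p = 0.533 with an estimated correlation) and T cell genes for 14 of 16 (14 adjusted over the list alone, median 4.96, camera adjusted p = 0.001, adjusted p = 0.533 with an estimated correlation). Plasma cell genes were higher for 16 of 17 (16 adjusted over the list alone), at a median log2 change of 3.39 (camera adjusted p = 6.13e-05, adjusted p = 0.533 with an estimated correlation). MYC targets were lower for 35 of 50 and higher for 1 (the same adjusted over the list alone), at a median of -0.56 (camera adjusted p = 3.47e-08, adjusted p = 0.533 with an estimated correlation). MYC itself was higher, and HK2 (-1.89 ± 0.24) and HSPD1 (-1.08 ± 0.15) were among those lower. Glycolysis genes were lower for 16 of 20 and higher for 2 (17 and 2 adjusted over the list alone), at a median of -1.89 (camera adjusted p = 1.78e-14, adjusted p = 0.234 with an estimated correlation). LDHA stood at 512 ± 122 CPM in tumors and 1920 ± 369 CPM in activated cells. Cell cycle genes went both ways, 7 higher and 8 lower of 34 (camera adjusted p = 0.478), with a median of 0.20 although the test pointed down, and TYMS changed by -1.64 ± 0.18 and CCNB2 by 1.29 ± 0.25. B cell genes also went both ways, 6 higher and 6 lower of 24, with FCER2 down (-2.31 ± 0.30) and FCRL1 up (1.82 ± 0.23), while with limma the counts were 1 and 11, in spleen tumors alone 1 and 1, and without mouse 1616 6 and 10. IL6-STAT3 genes were higher for 8 and lower for 10 of 24 (the same adjusted over the list alone), at a median of -0.40 (camera adjusted p = 0.0272, adjusted p = 0.425 with an estimated correlation). Unfolded protein response genes were higher for 22 of 31 and lower for 3 (23 and 3 adjusted over the list alone, camera adjusted p = 0.156), with CRELD2 up by 3.39 ± 0.61, or by 2.56 without mouse 1616. In spleen tumors alone 14 of these genes were higher, and 12 in limma with the mouse as a random block. With the level of Y-linked genes as a covariate, chosen after the values were seen, 4762 genes passed in all. Unfolded protein response genes were then higher for 1 and lower for 3, and plasma cell genes higher for 8 and lower for 0. B cell genes were higher for 5 and lower for 1, and cell cycle genes higher for 1 and lower for 8. IL6-STAT3 genes were higher for 5 and lower for 8 with this covariate. CCNB2 (adjusted p = 0.0747, over a range of 1.1e-06 to 0.0747) and MYC (adjusted p = 0.0825, over a range of 2.35e-11 to 0.0825) did not pass with it.

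Genes that differed from both control groups in 1 direction separate the tumor samples from resting and dividing B cells alike. There were 3811, of which 2416 were higher and 1395 lower in tumors. Markers of other cell types were higher in both comparisons, against quiescent and activated cells 13 and 14 of 14 macrophage, 9 and 9 of 9 neutrophil, 8 and 8 of 8 erythroid and 12 and 12 of 13 stromal genes. What part of the 2416 comes from such cells in the samples was not tested. The higher genes made up 63.4%, but 38.6% with quantile normalization and 95.1% with a filter of at least 2-fold. Higher than both were MYC, IL6R, SDC1, PRDM1, XBP1, MKI67 and IGHA1, and lower than both were PAX5, MS4A1, BCL2 and FCER2. Against activated cells several of these calls depend on the setting. With the level of Y-linked genes as a covariate, chosen after the values were seen, 1894 genes differed from both groups. The slope of that covariate rests on the tumor mice, so calls lost with it do not settle a dependence on the Y-linked level. MYC, PRDM1, XBP1, MKI67, PAX5, MS4A1 and BCL2 then did not pass against activated cells, at adjusted p of 0.0825, 0.392, 0.684, 0.452, 0.337, 0.229 and 0.225, each the highest over its alternatives (lowest 2.35e-11, 7.17e-06, 0.00726, 3.37e-05, 6.04e-06, 2.53e-05 and 9.31e-06). XBP1 also lost its call there without mouse 1616 (0.107). In spleen tumors alone XBP1, PAX5, MS4A1 and BCL2 did not pass either (0.134, 0.151, 0.186 and 0.0664), at log2 changes of 1.37, -1.47, -1.32 and -1.21, nor did PRDM1 and XBP1 in limma with the mouse as a random block (0.084 and 0.407). IL6R, the receptor for IL6, averaged 74.2 ± 23.1 CPM (SD, n = 8) in tumors, 27.0 ± 3.72 CPM (SD, n = 4) in quiescent and 18.2 ± 1.86 CPM (SD, n = 5) in activated cells. Its log2 changes were 1.46 ± 0.21 and 2.03 ± 0.20 (adjusted p = 2.33e-05 and 3.66e-07). A further 1405 genes passed against both groups in opposite directions, 755 of them between quiescent cells below and activated cells above. Both comparisons share the tumors, so some overlap follows from that alone. Independent lists of these sizes would share 1553 higher and 1002 lower genes. With the tumor mice parted into 4 for each comparison, so that no tumor was shared, the median over 20 partings was 3106.5 genes, from 2856 to 3455, with medians of 2110.5 higher and 1017.5 lower. Independent lists of the parted sizes would share medians of 1282 and 768, and 20 of 20 partings exceeded their own such values in each direction, a check chosen after the values were seen.

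The comparison of activated with quiescent B cells sets cells cultured with LPS against quiescent cells. The labels list no B cells cultured without LPS, so effects of LPS and of culture cannot be told apart. The groups also differ in Y-linked genes and in markers of other cells, given below. IL6 rose from 3 counts in quiescent cells to 62.1 ± 8.76 CPM (SD, n = 5), a ratio of 1550 (95% counting interval 531 to 7530, adjusted p = 2.51e-09). MYC rose by 1.60 ± 0.33 on the log2 scale (SE, adjusted p = 0.000517) and MKI67 by 3.66 ± 0.23 (adjusted p = 3.52e-09). CISH, an inhibitor of cytokine signaling, rose from 1.08 ± 0.696 CPM (SD, n = 4) to 445 ± 19.3 CPM (SD, n = 5), and SERTAD4 was at least 672-fold higher. CR2 fell from 2420 ± 189 CPM (SD, n = 4) to 100 ± 4.83 CPM (SD, n = 5), a log2 change of -4.59 ± 0.55 (adjusted p = 2.43e-06), and the lymphotoxin gene LTB changed by -4.21 ± 0.41. SDC1 (-4.44 ± 0.63, adjusted p = 1.64e-05), JCHAIN (-4.41 ± 0.68) and CD38 (-0.98 ± 0.16) were lower in activated cells, while PAX5, MS4A1, PRDM1 and IRF4 did not pass (adjusted p of 0.93, 0.722, 0.0924 and 0.435). Their lowest adjusted p over alternatives were 0.201, 0.0236, 4.58e-06 and 0.00154, so all but PAX5 passed in some setting. The log2 change ran from 0.67 to 2.21 for PRDM1 and from -0.44 to 1.02 for IRF4. XBP1 passed at an adjusted p of 0.0378 but lost its call when any control library was left out (0.0542 to 0.0774), over a range of 2.63e-12 to 0.175. IGHA1 (-2.88 ± 1.07, adjusted p = 0.0283) lost its call without activated library 1, 2 or 3 (0.0546, 0.0502 and 0.0618) or quiescent library 3 (0.0716), over a range of 4.31e-05 to 0.13. With the level of Y-linked genes as a covariate, chosen after the values were seen, its log2 change turned to 3.84 (adjusted p = 0.109), and SDC1 (-2.18, adjusted p = 0.0997) and JCHAIN (-2.64, adjusted p = 0.0942) lost their calls. That covariate parts activated from quiescent libraries fully, so this fit leans on its slope among the tumor mice and cannot settle these changes. CD38 lost its call in limma with the mouse as a random block (adjusted p = 0.0661). The lowest adjusted p over alternatives were 7.31e-15, 1.35e-10 and 3.16e-09 for SDC1, JCHAIN and CD38, and those values the highest. Without quiescent library 2 the log2 change of IL6 was 11.3, against 10.43.

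Over all genes, 6925 passed in edgeR, 2962 higher and 3963 lower in activated cells, and 6581 of the genes called had no overlap, against a chance share of 1.59% of genes. The higher genes made up 42.8%, and 50% with quantile normalization. In a fit of the control groups alone, 8741 passed. Glycolysis genes were higher for 18 of 20 and lower for 1 (the same adjusted over the list alone), at a median log2 change of 2.72 (camera adjusted p = 2.73e-17, adjusted p = 0.226 with an estimated correlation). HK2 rose by 4.14 ± 0.35 and LDHA by 3.18 ± 0.22. MYC targets were higher for 46 of 50 (46 adjusted over the list alone, median 1.46, camera adjusted p = 7.15e-26, adjusted p = 0.362 with an estimated correlation). Cell cycle genes were higher for 32 of 34 and lower for 1 (the same adjusted over the list alone, median 3.37, camera adjusted p = 3.45e-31, adjusted p = 0.263 with an estimated correlation). B cell genes were lower for 14 of 24 (15 adjusted over the list alone, median -0.98, camera adjusted p = 0.00828, adjusted p = 0.685 with an estimated correlation), while 7 were lower with quantile normalization, 4 with the 14 tumor libraries taken as independent and 2 in limma with the mouse as a random block. Plasma cell genes were higher for 1 and lower for 5 of 17 (0 and 5 adjusted over the list alone, camera adjusted p = 0.315), and 5 and 8 in the fit of the control groups alone. IL6-STAT3 genes were higher for 12 and lower for 4 of 24 (the same adjusted over the list alone, median 0.55, camera adjusted p = 0.00499, adjusted p = 0.362 with an estimated correlation). SOCS1, a brake on cytokine signaling, rose by 4.56 ± 0.21. Of 14 macrophage genes, 10 were lower in activated cells and 0 higher (camera adjusted p = 0.0161, adjusted p = 0.634 with an estimated correlation). The pancreas enzyme gene CPA1, among the largest falls, averaged 12.8 ± 14.7 CPM (SD, n = 4) in quiescent and 0 CPM in activated cells. Part of the difference may thus lie in other cells carried over into the quiescent libraries, which was not tested.

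Y-linked genes separated the control groups. DDX3Y averaged 0.133 ± 0.0803 CPM (SD, n = 5) in activated and 212 ± 9.57 CPM (SD, n = 4) in quiescent cells, a log2 change of -10.55 ± 1.39 (adjusted p = 7.1e-06), and KDM5D (-8.74 ± 1.27) and UTY (-7.31 ± 1.03) changed alike. The sum of the Y-linked genes lay between 0.581 and 1.01 CPM in activated and between 458 and 484 CPM in quiescent libraries. Among tumors it was 3.31 and 13.4 CPM in the MLN and spleen tumors of mouse 1613, 7.03 and 48.4 CPM in those of mouse 1614 and 5.43 CPM in the spleen tumor of mouse 1612, and between 201 and 415 CPM in the others. The labels give no sex. Comparisons with activated cells therefore hold the treatment and the Y-linked level together. Within each control group that level hardly varied, so the slope of the Y-linked covariate rests on the tumor mice and is carried over to control cells. Calls lost or turned with it cannot tell a dependence on the Y-linked level from a covariate that moves with the group.

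**Figure D2:**
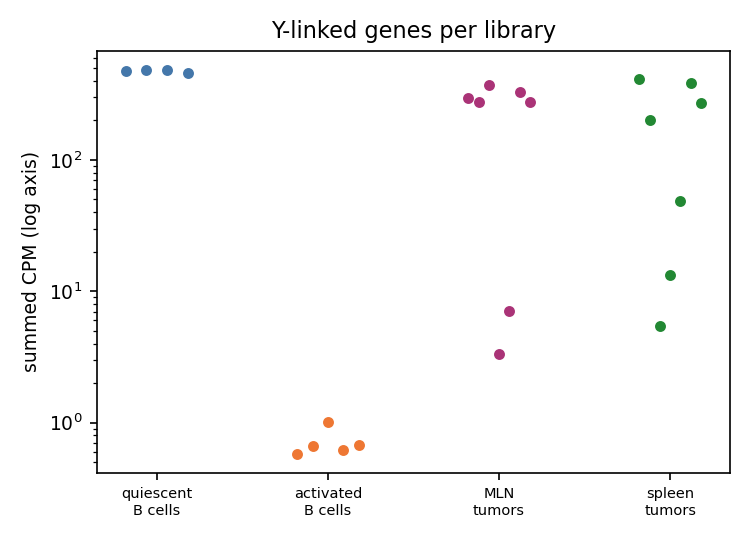
Summed CPM of Y-linked genes on a log axis in each library, by group. Activated libraries sit between 0.581 and 1.01 CPM and quiescent libraries between 458 and 484 CPM.

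**Figure D3:**
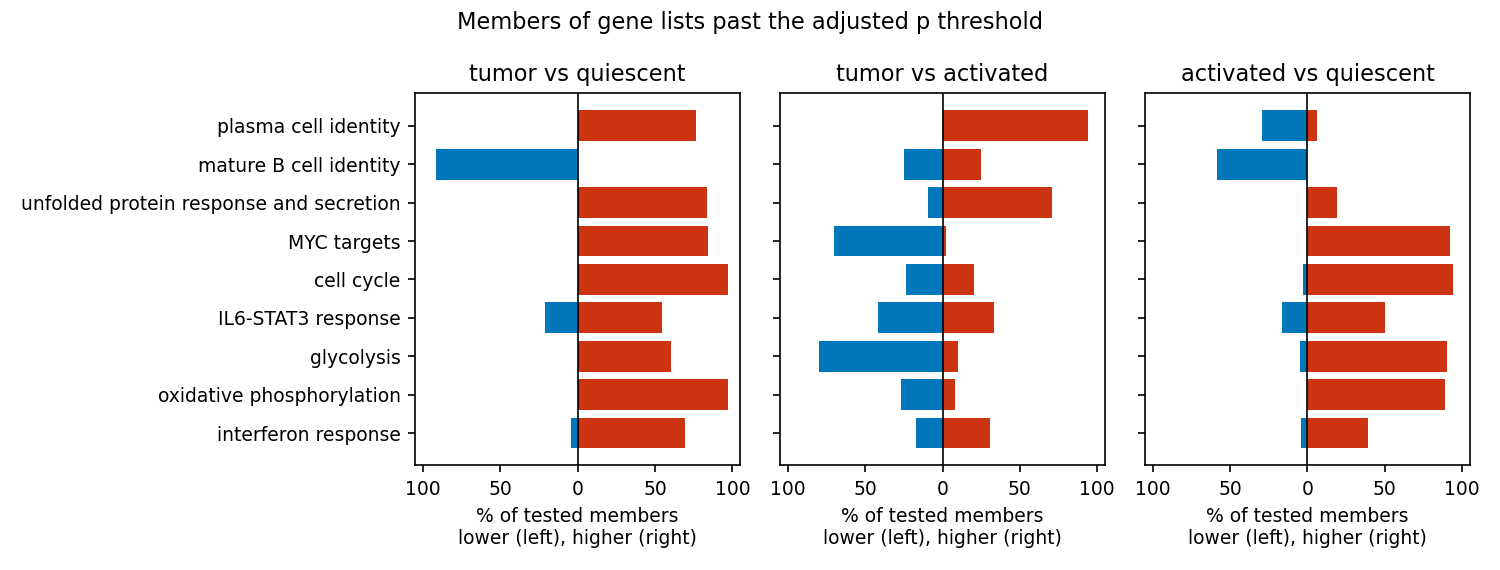
Percent of the tested members of 9 lists that passed the threshold in the 3 comparisons with or between control groups, lower to the left and higher to the right. Against quiescent cells, 33 of 34 cell cycle genes are higher in tumors and 32 in activated cells, while 35 of 50 MYC targets are lower in tumors than in activated cells.

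The comparison of MLN with spleen tumors asks whether the tissue of a tumor shows in its expression. MYC averaged 929 ± 473 CPM (SD, n = 7) in MLN and 803 ± 652 CPM (SD, n = 7) in spleen tumors, a log2 change of 0.21 ± 0.47 (SE, adjusted p = 1). SDC1 differed by 0.73 ± 0.78, XBP1 by 0.17 ± 0.79 and IGHA1, at 67100 ± 104000 against 22000 ± 44600 CPM, by 1.61 ± 1.37, each at an adjusted p of 1. The log2 change of IGHA1 ran from 0.64 to 3.83 over alternatives. Among spleen tumors IGHA1 took 11.6% of the counts in mouse 1611 and 0.138% to 2.55% in the others. In edgeR 0 of 11637 genes passed, and 511 had an unadjusted p under 0.05, fewer than chance gives on average at that threshold. With limma and with the exact Wilcoxon test 0 passed, with DESeq2 20 (16 higher and 4 lower in MLN tumors), and with the mouse as a block over 6 pairs 0 (smallest adjusted p 0.275, 350 at an unadjusted p under 0.05). Chosen after the values were seen, the collagen gene COL3A1 (log2 change 4.91 in DESeq2, adjusted p = 0.000312) had the largest rise and the smallest adjusted p, LUM, COL6A2, COL1A1 and COL1A2 were also higher, and the erythroid gene CA1 was among the lower (-4.28, adjusted p = 0.0389). In edgeR COL3A1 changed by 4.86 ± 1.11 at an adjusted p of 1.

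Of the list tests between the tissues, 0 passed with an estimated correlation. With the preset correlation several did. Stromal genes were higher in MLN tumors at a median of 2.33 (7 of 13 adjusted over the list alone and 0 over all genes, camera adjusted p = 4.17e-10, adjusted p = 0.234 with an estimated correlation). T cell genes were higher at a median of 1.86 (0 of 16 by either count, camera adjusted p = 8.14e-08, adjusted p = 0.498 with an estimated correlation). Their mean log2 level was 6.01 in the MLN tumor of mouse 1610 and 1.43 to 3.85 in the other MLN tumors, and in mice 1614 and 1616 it was higher in the spleen tumor (3.67 against 3.41 and 2.85 against 1.43). Erythroid genes were higher in spleen tumors, at a median of -2.73 (2 of 8 adjusted over the list alone and 0 over all genes, camera adjusted p = 3.23e-15, adjusted p = 0.234 with an estimated correlation). Neutrophil genes were too, at -3.00 (6 of 9 and 0, camera adjusted p = 1.8e-07, adjusted p = 0.425 with an estimated correlation), and platelet genes at -1.91 (0 of 5 by either count, camera adjusted p = 8.14e-08, adjusted p = 0.226 with an estimated correlation). With fry the erythroid and platelet lists passed (adjusted p = 0.0411 and 0.0185, the ranges over alternatives running from 1.41e-28 to 0.234 and from 6.37e-09 to 0.226), and the stromal, T cell, neutrophil and plasma cell lists did not (0.0748, 0.274, 0.196 and 0.404). These tests leave the pairing out. In each of the 6 pairs, looked at after the values were seen, the mean level of stromal genes was higher in the MLN tumor. That of erythroid and platelet genes was higher in the spleen tumor in each pair. Neutrophil genes were higher in the MLN tumor in mice 1610 and 1615. With the mouse as a block the stromal list had a camera adjusted p of 6.34e-21 with the preset correlation. Plasma cell genes leaned to MLN tumors at 0.56 (0 of 17 by either count, camera adjusted p = 7.37e-06, adjusted p = 0.533 with an estimated correlation). Of the core lists, those of the unfolded protein response (0 of 31 by either count, median 0.35, camera adjusted p = 5.57e-05, adjusted p = 0.638 with an estimated correlation) and MYC targets (0 of 50, median 0.09, camera adjusted p = 0.00185, adjusted p = 0.666 with an estimated correlation) leaned to MLN tumors. So did the IL6-STAT3 list (0 of 24, median 0.20, camera adjusted p = 0.00634, adjusted p = 0.425 with an estimated correlation), and cell cycle genes leaned to spleen tumors (0 of 34, median -0.28, camera adjusted p = 0.000115, adjusted p = 0.644 with an estimated correlation). None of these 4 passed with fry. Interferon genes leaned to spleen tumors (0 of 23, median -0.91, camera adjusted p = 3.58e-05, adjusted p = 0.533 with an estimated correlation). The spleen tumors of mice 1611 and 1614 had the highest mean log2 levels of these genes (6.93 and 7.18, the other spleen tumors 4.27 to 5.23), and also of neutrophil (6.88 and 6.94) and erythroid genes (8.39 and 7.68). The B cell list did not pass (adjusted p = 0.138, but 0.00594 with the mouse as a block, over a range of 0.00594 to 0.831), with a median of -0.17 and a mean of -0.19 although the test pointed up, and its median was 0.67 with quantile normalization.

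**Figure D4:**
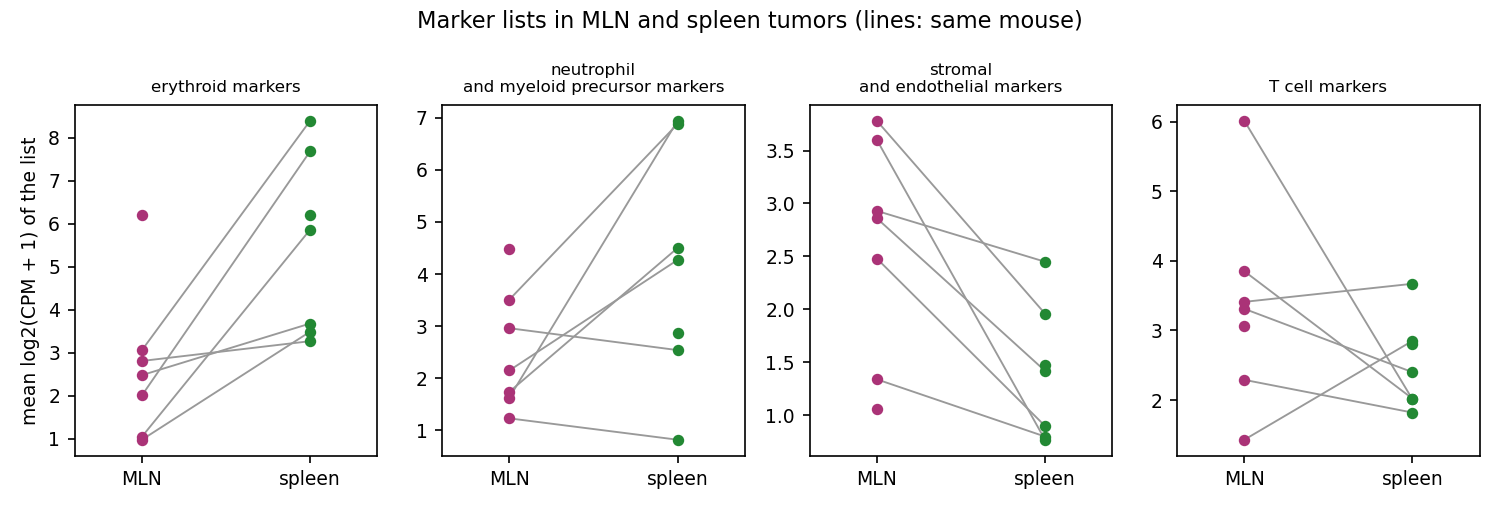
Mean log2 level of 4 marker lists in the MLN and spleen tumors, with lines between tumors of 1 mouse. HBA1, the most abundant erythroid marker, averaged 674 CPM in spleen and 146 CPM in MLN tumors (841 in mouse 1609, 7.98 to 80.1 in the others), and COL3A1, the most abundant stromal marker, 2.57 and 76.2 CPM.

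V gene usage bears on whether tumors hold 1 dominant clone and whether a mouse's tumors share it, because each B cell clone carries its own rearranged V genes. The commonest IGHV profile took 63.3% ± 23.7 (SD, n = 8 mice) of heavy chain V counts in tumors and 34.8% ± 5.66 (SD, n = 4) in quiescent cells, 28.6 points more (exact permutation p = 0.0364), with 7 of 8 mice above every quiescent library. Activated cells had 38.4% ± 2.73 (SD, n = 5), 24.9 points less than tumors (exact permutation p = 0.0373). The commonest IGKV profile took 51.1% ± 27.7 (SD, n = 8 mice) of kappa V counts in tumors and 20.7% ± 15.7 (SD, n = 4) in quiescent cells, 30.4 points more (exact permutation p = 0.0525, 4 of 8 mice above every quiescent library). This was 36.7 points more than the 14.4% ± 2.24 (SD, n = 5) of activated cells (exact permutation p = 0.00155, 8 of 8 mice above), but in spleen tumors alone it did not pass (28.7 points, exact permutation p = 0.0606). In the spleen tumor of mouse 1616 the commonest IGKV profile took 99.9% (95% Wilson interval 99.8% to 99.9%) and in the MLN tumor of mouse 1614 98.0% (98.0% to 98.1%). Single tumors also lay at the level of control libraries, with 10.6% (9.78% to 11.4%) in the spleen tumor of mouse 1615, 10.9% (10.2% to 11.7%) in that of mouse 1610 and 14.5% (13.8% to 15.3%) in the MLN tumor of mouse 1611. The MLN and spleen tumors of a mouse overlapped in IGKV usage by 0.547 on average, against 0.290 over all 720 pairings (1-sided exact permutation p = 0.0139), and in IGHV usage by 0.769 against 0.647 (p = 0.0806, exact permutation). IGKV overlap was 0.954 in mouse 1616 and 0.053 in mouse 1614. The commonest IGHV profile was the same in 9 of 9 control libraries and 11 of 14 tumors, so it does not tell clones apart. Of 6 mice with both tumors, 4 had 1 commonest IGHV profile in both, and 2 (1613 and 1616) 1 commonest IGKV profile. The IGHV difference from quiescent cells did not pass without quiescent library 1, 3 or 4 (exact permutation p = 0.109, 0.0606 and 0.0727), nor that from activated cells without activated library 1, 3, 4 or 5 (0.0606, 0.0687, 0.0768 and 0.0687). The IGKV difference from quiescent cells passed without quiescent library 2 (exact permutation p = 0.0121). The shared IGKV usage did not pass without mouse 1613 or 1616 (exact permutation p = 0.0833 for each), and shared IGHV usage passed without mouse 1614 (exact permutation p = 0.0333). The table holds 15 IGHV and 24 IGKV profiles under ortholog names, so distinct mouse V genes may share 1 profile, and others may have none. V counts were few beside those of constant genes in some tumors. The spleen tumor of mouse 1611 had 2940 IGKV counts with IGKC at 5.78% of its total. Quiescent library 1 had 22739 with IGKC at 0.642%. Shares and overlaps in such tumors may leave out the V genes of the main clone.

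**Figure D5:**
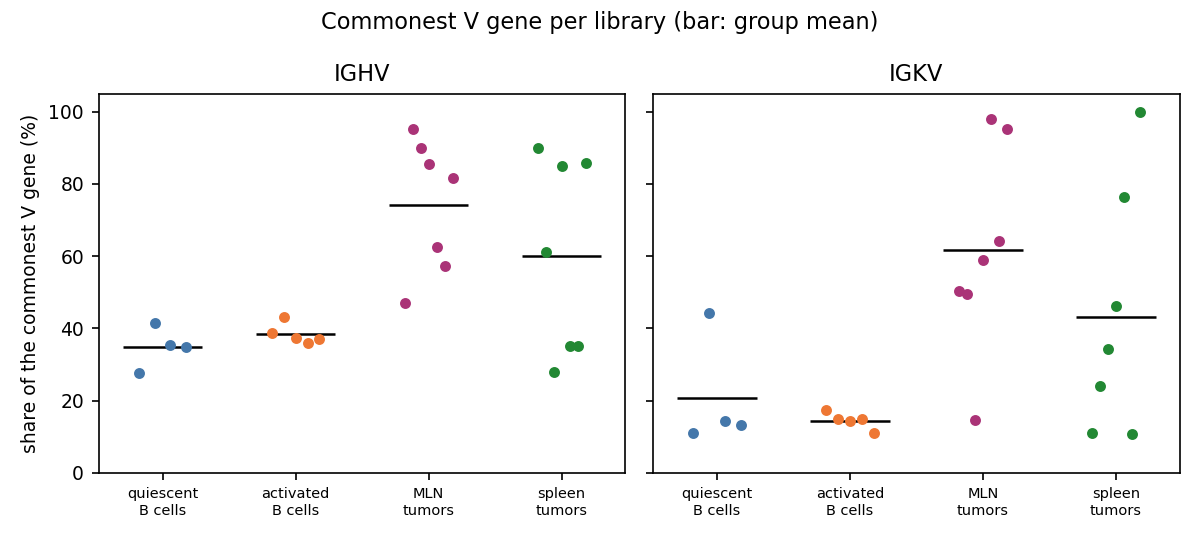
Share in percent of the commonest IGHV and IGKV profile in each library, with a bar at each group mean. Over their tumors, the 8 mice average 63.3% for IGHV and 51.1% for IGKV, and quiescent libraries 34.8% and 20.7%.

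Whether a mouse's tumors resemble each other over all genes, and whether MYC moves with the core lists, was asked across tumor mice. The correlation of MLN and spleen tumors of 1 mouse, as deviations from the tissue means, averaged -0.00387 over 6 mice, no higher than other pairings gave (1-sided exact permutation p = 0.496). MYC rose with the unfolded protein response genes over 8 mice (Pearson r = 0.97, exact permutation p = 0.000422, adjusted p = 0.00253 by Benjamini-Hochberg over 6 lists; Spearman rho = 0.95, permutation p = 0.00114, adjusted p = 0.00685). Without mice 1616 and 1609, which lay farthest from the median MYC, r was 0.96. MYC also rose with the plasma cell genes (r = 0.95, exact permutation p = 0.00109, adjusted p = 0.00327), but rho was 0.76 (permutation p = 0.0368, adjusted p = 0.11), and r without those mice 0.91. It did not pass with B cell genes (r = -0.80, exact permutation p = 0.0312, adjusted p = 0.0623), MYC targets (r = 0.66, adjusted permutation p = 0.12), cell cycle genes (r = -0.41, adjusted permutation p = 0.384) or the IL6-STAT3 list (r = 0.15, adjusted permutation p = 0.725). Plasma cell and B cell genes correlated at r = -0.85 over the mice (Spearman rho = -0.38). The correlations with MYC cannot tell levels within tumor cells from the makeup of the samples.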

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

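No test here was chosen after the result was seen, and no explanation was tested for these results. Each is a library that lies far from the others of its group by Dixon's test, which was run 104 times and picks about 1 in 20 groups by chance. Values of genes are log2 CPM.

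The plasma cell surface gene SLAMF7 stood at 7.91 in the spleen tumor of mouse 1616, the nearest other spleen tumor at 6.57, and CCND3, a cyclin of dividing lymphocytes, at 5.76 in the same library, the nearest at 7.09. Among quiescent libraries, IRF4 stood at 7.75 in library 4 (nearest 7.99), SLAMF7 at 5.67 in library 1 (nearest 5.82) and MKI67 at 4.58 in library 3 (nearest 4.71). Among activated libraries, IGHA1 stood at 3.24 in library 3 (nearest 4.99). The commonest IGKV profile took 44.1% of kappa V counts in quiescent library 2, and at most 14.3% in the other quiescent libraries. Without that library the difference in IGKV share between tumors and quiescent cells was 38.3 points, against 30.4 with it.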

How the results depend on the processing

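The edgeR test was chosen after the data were seen, which made limma, the test of the design, a later alternative. DESeq2, the Y-linked level as a covariate and leaving out the spleen tumor of mouse 1614 were chosen after the data were seen too. Planned settings in TPM were run in CPM, with library totals in place of TPM as deposited. Of the counts and tests, 166 planned and 15 later alternatives kept. A count kept if its total stayed within 1.5 times, and a test if its direction and its side of the threshold stayed. Of the others, 7 and 3 moved by more than 1.5 times, 4 passed newly, 13 no longer passed and 8 reversed. The share of higher genes was not part of this. For tumor vs both controls quantile normalization kept by its total, while that share went from 63.4% to 38.6%. Of the list tests 266 kept, 27 passed newly, 81 no longer passed and 3 reversed, and of the named genes, by library totals, a pseudocount of 0.1 or the mouse as a block only, 629 kept, 3 passed newly, 9 no longer passed and 11 reversed. Apart from the counts with a fold filter or fewer samples, the cause was not tested.

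A filter of at least 2-fold left 3579 genes for tumor vs quiescent, 3366 for tumor vs activated, 3218 for activated vs quiescent and 2055 for tumor vs both controls, and spleen tumors alone left 2501 for both controls. With the Y-linked covariate 4762 passed for tumor vs activated and 1894 for both controls. For MLN vs spleen tumors DESeq2 called 20 and edgeR 0. Leaving out 1 mouse or control library gave 7353 to 8369 genes for tumor vs quiescent, 6812 to 8199 for tumor vs activated, 3488 to 4243 for both controls and 6408 to 6611 for activated vs quiescent. In all such fits 6923, 6344 and 5948 genes kept their call in the 3 comparisons, and 0, 1 and 1 turned. Of the gene list tests 0 passed with an estimated correlation.

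For the same-mouse resemblance, the 2000 most variable genes gave 0.0068, and leaving out 1 mouse gave -0.194 to 0.145 (0.0311, 0.0783, 0.0279 and 0.145 without 1610, 1611, 1614 and 1615), each near 0. For the same-mouse immunoglobulin V usage, leaving out 1 mouse gave overlaps of 0.724 to 0.82 for IGHV, which passed without 1614, and 0.466 to 0.646 for IGKV, which did not pass without 1613 (0.497) or 1616 (0.466). For the dominant V segment share, spleen tumors alone gave differences of 25.2 points (IGHV, quiescent), 21.5 (IGHV, activated) and 28.7 (IGKV, activated), none of which passed, and MLN tumors alone 40.9 (IGKV, quiescent), which passed. Leaving out 1 control library gave 26.2 to 30.8 and 24.3 to 26.1 for IGHV, and 27.2 to 38.3 for IGKV against quiescent cells. Without the mice farthest from the median MYC, 1 of the MYC correlations passed instead of 2, and that with cell cycle genes was 0.28. By library totals those with MYC targets and the IL6-STAT3 list were -0.15 and -0.32.

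The reversed list tests are those of myeloma-associated genes, in tumor vs activated with fry (adjusted p = 0.17) and by library totals (0.992), and in activated vs quiescent with fry (0.765). Under other settings further named genes lost calls or turned, as XBP1 in tumor vs activated, which lost its call in 17 settings and was -0.46 with the Y-linked covariate. By library totals CCND3 in tumor vs activated changed by 0 and PAX5 in activated vs quiescent by 0.04, and with a pseudocount of 0.1 in limma they changed by -0.16 and 0.02. In MLN vs spleen tumors, that pseudocount and the mouse as a block gave 0.88 and 1.12 for PAX5, 0.74 and 0.95 for MS4A1, and 0.25 and 0.16 for BCL2, and the pseudocount 0.13 for IL6R. Replicate numbers as a block over 4 pairs of activated and quiescent libraries gave 8426 genes, against 8627 of the same 8 libraries without it, and libraries of equal number did not match better than others (-0.01, -0.01, -0.02 and 0.0). At 1.5-fold, 1.5% of simulated changes were found between MLN and spleen tumors, for a cause not tested.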

Other observations

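The tests of Y-linked genes, of markers of other blood cells and of libraries of about equal depth were chosen after the result was seen, as were edgeR, the Y-linked covariate, DESeq2 and limma as an alternative. Several lists differed between tumors and quiescent cells beyond the core lists. Amino acid and one-carbon genes were higher for 21 of 23 (21 adjusted over the list alone, median log2 change 1.92, camera adjusted p = 2.4e-05, adjusted p = 0.533 with an estimated correlation). The asparagine enzyme ASNS rose from 2.94 ± 1.17 CPM (SD, n = 4) to 110 ± 94.2 CPM (SD, n = 8). Genes of oxidative phosphorylation were higher for 36 of 37 (36 adjusted over the list alone, median 0.57, camera adjusted p = 1.25e-07, adjusted p = 0.533 with an estimated correlation). Glycolysis genes were higher for 12 of 20 (12 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.533 with an estimated correlation). Ribosomal proteins were higher for 57 of 58 (57, and 1 lower, adjusted over the list alone, camera adjusted p = 1.89e-09, adjusted p = 0.533 with an estimated correlation). NF-kB targets were lower for 12 of 20 (11 adjusted over the list alone, camera adjusted p = 0.00185, adjusted p = 0.577 with an estimated correlation), with LTA at -2.36 ± 0.33. Polycomb and chromatin genes were lower for 13 and higher for 4 of 24 (the same adjusted over the list alone, camera adjusted p = 0.00634, adjusted p = 0.533 with an estimated correlation), with EZH2 up by 1.53 ± 0.28.

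Other lists did not pass in camera against quiescent cells. These were interferon response (16 higher and 1 lower of 23, the same adjusted over the list alone, adjusted p = 0.0618), B cell activation (11 and 4 of 23, adjusted p = 0.083) and the BCL2 family (7 and 3 of 13, adjusted p = 0.363). Further ones were trafficking and adhesion (7 and 11 of 22, adjusted p = 0.61) and drug and antibody targets (3 and 9 of 20, adjusted p = 0.218), with the same counts adjusted over the list alone. Myeloma-associated genes split evenly, 9 higher and 9 lower of 23 (the same adjusted over the list alone, adjusted p = 0.858), with a median of -0.02 that was 0.03 by library totals, 0.01 with quantile normalization and 0.05 with DESeq2, and a mean of 0.68. With fry, B cell activation, the BCL2 family, drug and antibody targets and intestinal epithelium genes passed (adjusted p = 0.000349, 0.00195, 2.8e-05 and 0.00122). In camera with an estimated correlation the adjusted p of these lists were 0.533, 0.581, 0.533 and 0.533. The sphingosine receptor S1PR2 rose from 4.57 ± 1.25 to 73.2 ± 31.9 CPM (adjusted p = 4.85e-07). Exocrine pancreas genes were lower in tumors for 5 of 8 (6 adjusted over the list alone, camera adjusted p = 0.328), and CELA2A and PNLIP lost their calls without quiescent library 2 (adjusted p = 0.0764 and 0.132, the ranges over alternatives reaching 0.194 and 0.332). Intestinal epithelium genes were higher for 3 of 3 (3 adjusted over the list alone, camera adjusted p = 0.075), EPCAM reaching 220 CPM on average in tumors, from 6.55 to 1000, against 5.83 in quiescent and 24 in activated cells. Their mean log2 level was highest in the spleen tumor of mouse 1616 (7.26) and the MLN tumors of 1610 and 1616 (6.48 and 6.44). It was lowest in the spleen tumors of 1610 and 1615 (1.26 and 1.57). Plasma cell genes stood at 9.32, 8.89, 9.15, 5.08 and 5.41 there, chosen after the values were seen. Which cells express these genes was not tested. The only adipocyte gene tested, FABP4, was higher (5.57 ± 1.36, adjusted p = 0.002), and 7.30 without quiescent library 1.

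Y-linked genes were near 0 in the activated cells. A candidate explanation is that the control B cells came from mice of different sex, and the highest activated library stood at 0.22% of the lowest quiescent one, as this requires. An effect of LPS on Y-linked genes remains open, because treatment and control group coincide, although 4 tumor libraries, none of them cultured, were also under 5% of the quiescent mean. The spleen tumor of mouse 1614 was at 10.2% of that mean, between the others. Sex of the animals was not tested against any outcome.

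Markers of other blood cells were higher in tumors than in quiescent cells despite the negative selection, which would remove such cells. Macrophage genes were higher for 13 of 14 (13 adjusted over the list alone, camera adjusted p = 0.00077, adjusted p = 0.533 with an estimated correlation). C1QB reached 627 CPM on average against 7.64 in quiescent cells, with a log2 change of 6.12, or 6.77 without quiescent library 4, and 12 of the 14 stand at 1 CPM or more in quiescent cells as well. Neutrophil genes were higher for 9 of 9 (9 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.577 with an estimated correlation). S100A8 averaged 152 CPM in tumors, from 2.88 to 907, against 0.432. Erythroid genes were higher for 8 of 8 (8 adjusted over the list alone, camera adjusted p = 0.0127, adjusted p = 0.533 with an estimated correlation). HBA1 averaged 410 CPM in tumors, from 7.98 to 2000, against 8.77. Cells of these types left in the tumor samples may account for this. The members of each list moved together over tumors more than those of 100% of 10000 random lists (the lowest of the 3 lists). Members of a marker list can move together whichever cells express them, so this cannot tell left-over cells from expression by malignant cells. That the malignant cells express these genes stays open, because the plasma cell list went with the 3 lists at Spearman correlations of at most -0.21 over 8 mice, too few to exclude it. T cell genes went the same way (11 higher and 1 lower of 16, the same adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.666 with an estimated correlation). So did stromal genes (12 of 13, 12 adjusted over the list alone, adjusted p = 0.0302, adjusted p = 0.533 with an estimated correlation) and dendritic cell genes (7 of 9, 7 adjusted over the list alone, adjusted p = 0.046, adjusted p = 0.533 with an estimated correlation). NK (6 higher and 1 lower of 8, the same adjusted over the list alone, adjusted p = 0.0768) and platelet genes (4 of 5, 5 adjusted over the list alone, adjusted p = 0.128) did not pass in camera but did in fry (adjusted p = 0.000494 and 0.000462). In camera with an estimated correlation their adjusted p were 0.533 and 0.567.

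B cell identity genes were spread widely between the tumors. Polyclonal B cells mixed into the samples could raise these genes and lower the share of 1 clone. The B cell score and the commonest IGKV share had a Spearman correlation of -0.52 over 8 mice (exact permutation p = 0.197), which leaves this open. Pearson's r was -0.83 (exact permutation p = 0.0105) but 0.06 without the 2 mice farthest from the median, so it rests on those. Sequencing depth is not the whole cause. Among the 5 tumor libraries within 5% of the median total, scores ran from 3.38 to 9.05, and with any 1 of them left out their SD was at least 67% of that over 14 libraries. A part played by depth stays open, with a Spearman correlation of 0.38 between the score and the total count over 14 libraries. No biological explanation was tested.

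Other splits of the samples speak against a chance split of the libraries for 4 comparisons, and against no more than that. Any other split mixes libraries of different groups, which widens the spread within its groups, and the median of the other splits was 0 genes in each. The splits therefore do not bear on how many of the calls are right or on their cause. They take each control library as a separate unit, which the labels do not state. Chance differences between the animals behind the control groups are therefore not excluded. Of 100 splits, only the real 1 gave as many genes in tumors against quiescent cells (7333 in a fit of the groups compared, highest other 1) and tumors against activated cells (6901, highest other 2245). The same held for both controls (3811, highest other 0) and activated against quiescent cells (8741, highest other 5540). For MLN against spleen tumors the real split gave 0 genes, as did the highest other of 64 splits that part the 6 pairs, and since every split reaches 0, they decide nothing about chance. The count there was 0 by edgeR, 20 by DESeq2 and 0 by limma. In edgeR 511 genes had an unadjusted p under 0.05, fewer than chance gives on average.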
